A study of Mus musculus with 8 samples.

How the data were processed

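Exosomal small RNA was measured in 8 mouse libraries, 1 for each combination of fluid (plasma or CSF), sex and treatment (baseline or DOCA-salt). Per the labels' protocols, total RNA was extracted with a Qiagen miRNeasy Micro kit, libraries were made with the QIAseq miRNA kit with UMIs, and single-end reads of 150 bp were sequenced on an Illumina NovaSeq. The authors trimmed reads with Cutadapt 2.7 and aligned them with Bowtie 1.3.0 to miRBase, piRNABank and Rfam, naming the builds mm10 and GRCm38 and naming edgeR for normalisation without a version or parameters. The deposited UMI columns hold counts, unique identifiers per mature miRNA and library, without scaling. The deposited read columns hold counts of reads before identifiers were collapsed. The deposited CPM columns hold cpm, the UMI count scaled to the library total as CPM, as recomputed from the files.

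Plasma had 1977 miRNAs and CSF 1961, of which 1960 were shared. UMIs never exceeded reads. CPM differed from the recomputed value in 2 CSF rows, where the deposited CPM of miR-1a-3p and miR-206-3p stand in each other's rows relative to both UMIs and reads. UMI rows were used as labelled, with exchanged labels as an alternative. Coordinates deposited with the miRNAs were checked against GENCODE M21 on mm10, and 1904 of 1965 lay inside an annotated miRNA gene on the same strand. Host genes were taken from that annotation. Counts of the pairs miR-199a-3p and miR-199b-3p, miR-486a-5p and miR-486b-5p, miR-133a-3p and miR-133b-3p, and in CSF miR-3473b and miR-3473e were nearly equal, and whether reads were shared within a pair is not known.

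Total UMIs per library ran from 158572 to 1082504 and reads from 301241 to 1833069. Shares of a single library carry 95% exact Clopper-Pearson intervals, and ratios of a pair carry exact conditional binomial intervals. A count of 0 entered a ratio through the prior count given below. A floor of 3 counts per library and miRNA set only the bounds of the test of muscle tissue in CSF. Molecular identifiers make counts closer to independent molecules than reads, but intervals do not cover differences between mice or preparations.

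Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. UMI counts were filtered with filterByExpr, scaled by TMM and fitted with edgeR's quasi-likelihood model, with Benjamini-Hochberg adjustment and a threshold of 0.05. CSF was compared with plasma over all 8 libraries with fluid as the only term (6 residual degrees of freedom). DOCA-salt against baseline and male against female were tested within each fluid with sex and treatment as terms, which leaves 1 residual degree of freedom, so spread was largely borrowed across miRNAs and an effect that differs by sex counts as spread. The difference of the DOCA-salt effect between fluids was the interaction term in a fit of all libraries with 2 residual degrees of freedom, and the same fit gave the difference of the sex effect, which was added after the data were seen. A sex-by-treatment difference within a fluid cannot be tested with 1 library per combination. Ratios of 1 library to 1 used TMM-scaled CPM, a prior count of 1, at least 50 UMIs over the pair and a 2-fold limit, and carry no test.

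Lists of miRNAs covered erythrocytes, liver, cardiac and skeletal muscle, platelets, leukocytes, endothelium, smooth muscle, neurons, glia, choroid plexus and ciliated epithelium, keratinocytes and other epithelium, the renin-angiotensin-aldosterone system and blood pressure, inflammation, fibrosis, the let-7, miR-30 and miR-17 families, the Dlk1-Dio3 imprinted cluster and the X chromosome, 19 in all. Lists with at least 3 measured members were tested with limma's camera, two-sided, with a preset correlation of 0.01 and again with an estimated one, adjusted by Benjamini-Hochberg over the lists of a comparison. A list's median in a single pair was ranked among 10000 random lists matched on expression.

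The rule for named miRNAs took those with a mean of at least 20 UMIs, up to 10 per direction of largest fitted change among those past the threshold with the same direction in every pair, or else the 3 of lowest p per direction, said not to pass. It added the 5 most abundant miRNAs per fluid, the 5 largest rises and falls of each pair, the 5 of highest mean count moved the same way or opposite ways in both sexes, up to 4 members of highest count per list, and miR-451a and miR-23a-3p. Comparisons, lists, this rule and the first group of alternative settings below were fixed before the data were examined.

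Alternative settings were DESeq2's size factors in edgeR, total-count scaling, DESeq2's Wald test, no count filter, the erythrocyte list left out, other models (sex and treatment as terms, a block per condition, a joint fit of both fluids, only the term tested), each library left out in turn, an estimated correlation, a prior count of 5, and pair minimums of 20 and 200 UMIs. Added after seeing the data were read counts in place of UMIs, exchanged CSF labels of miR-1a-3p and miR-206-3p, the muscle list left out, a minimum mean of 100 UMIs, and libraries thinned to 158572 UMIs.

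The procedure was tested on simulated data, 10 sets per comparison with the same design and depth. Of miRNAs changed 4-fold, 96.1% were recovered between fluids, 82.9% and 60.0% for DOCA-salt in plasma and CSF, and 51.3% and 52.0% for sex in plasma and CSF. Of those changed 2-fold, 31.5%, 17.8%, 11.5%, 9.24% and 8.11% were recovered in the same order. These are means over sets. At either size none were recovered in 2 of 10 sets for DOCA-salt in CSF, 3 for sex in plasma and 2 for sex in CSF. A raised muscle list ranked first by camera in all 10 sets of each comparison, and with an estimated correlation it was called only between fluids. Simulated miRNAs were drawn independently, so members of a list did not vary together. These sets therefore cannot show whether list calls with the preset correlation hold where members do vary together. In the data the correlation estimated between fluids ran from 0.0575 (X chromosome) to 0.839 (let-7). Reads aligned to piRNABank and Rfam were not in the deposited tables and target predictions were not attempted.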

Results

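Small RNA was sequenced from exosomes, vesicles that cells release into body fluids, isolated from the plasma and the cerebrospinal fluid (CSF) of adult wild-type mice. Mice were female or male, and were either untreated (baseline) or had received deoxycorticosterone acetate with salt (DOCA-salt), a mineralocorticoid treatment used to raise blood pressure. Each combination of fluid, sex and treatment was represented by 1 library, so the 8 libraries comprised 4 of plasma and 4 of CSF, all in batch 1. Molecules were counted by unique molecular identifiers (UMIs) for mature miRNAs, of which 1960 were listed in both fluids. Plasma libraries held 279864 UMIs in the baseline female, 337240 in the DOCA-salt female, 158572 in the baseline male and 304696 in the DOCA-salt male. CSF libraries held 237878 and 303625 UMIs in the baseline and DOCA-salt females, against 753144 and 1082504 in the baseline and DOCA-salt males. Intervals given here cover counting error only. As each combination had 1 library, p-values rest on differences between unlike libraries, within a fluid largely borrowed across miRNAs. They do not measure the spread between mice of a combination. The labels state 8 mice without saying which mice or pools gave each library.

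The 2 fluids differed in what filled their libraries. Members of the cardiac and skeletal muscle list, which holds miR-1, miR-133, miR-206 and the myosin-encoded miRNAs, made up 45.2% ± 9.46 of CSF UMIs (SD, n = 4) and 0.764% ± 0.522 of plasma UMIs (n = 4). The erythrocyte list, which holds miR-16-5p, miR-486a-5p and miR-451a, took 16.2% ± 3.95 of plasma and 3.62% ± 1.24 of CSF. Members of the let-7 family, regulators of developmental timing, took 23.9% ± 0.333 of plasma and 11.4% ± 2.91 of CSF. miR-183-5p, a miRNA of sensory epithelia, took 4.0% ± 3.31 of CSF and 0.0444% ± 0.0318 of plasma. The neuron list had like shares, 0.283% ± 0.0603 in CSF and 0.282% ± 0.0699 in plasma. Liver-list miRNAs took 0.378% ± 0.0948 of plasma and 0.0993% ± 0.0320 of CSF. The 10 most abundant miRNAs held 66.8% ± 8.20 of CSF and 45.0% ± 3.54 of plasma UMIs. The ratio of miR-451a to miR-23a-3p, used as a sign of red-cell RNA, was between 0.127 and 0.226 in plasma and between 0.0605 and 0.505 in CSF, where the baseline male was highest (95% exact Clopper-Pearson interval 0.467 to 0.546).

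**Figure D1:**
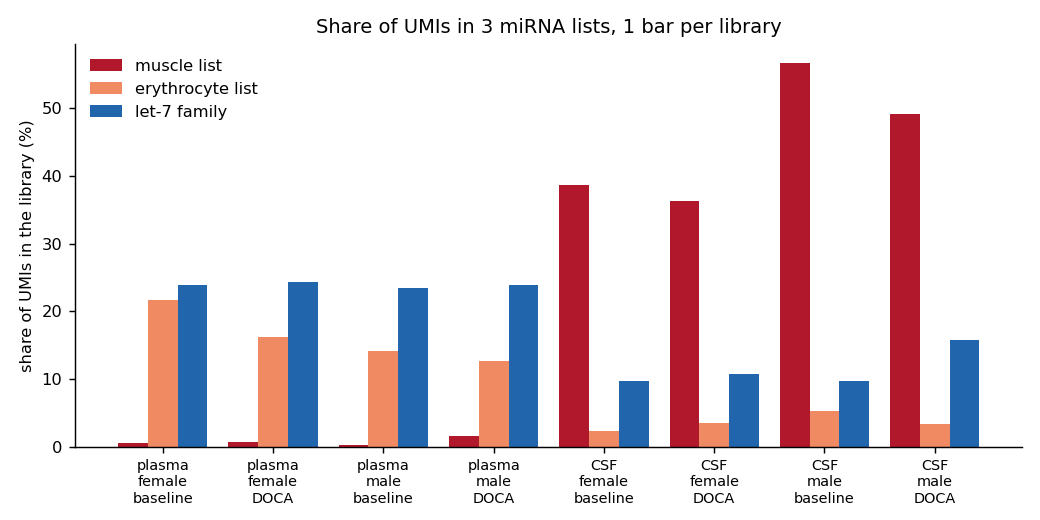
Share of UMIs (percent) in each of the 8 libraries taken by the cardiac and skeletal muscle list, the erythrocyte list and the let-7 family. Muscle-list shares ran from 36.3 to 56.7% in the 4 CSF libraries and from 0.293 to 1.51% in the 4 plasma libraries.

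In the CSF table the count rows of miR-1a-3p and miR-206-3p are uncertain, because their deposited CPM values stand in each other's rows. The opposite strands miR-1a-1-5p and miR-1b-5p kept a near-constant ratio to the count row labelled miR-206-3p (SD of the log2 ratio 0.17 and 0.23 over 4 libraries) and not to the row labelled miR-1a-3p (2.13 and 2.16). This pattern speaks for exchanged count labels, under which the labels of the deposited CPM would be right, but does not settle it. CSF values below still follow the labels of the count rows, with exchanged labels as an alternative.

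The comparison of fluids asked which exosomal miRNAs distinguish CSF from plasma. Muscle miRNAs stood far higher in CSF: miR-133a-3p was 154-fold and miR-133b-3p 158-fold higher, the count row labelled miR-206-3p 316-fold, and that labelled miR-1a-3p 138-fold (4 libraries against 4). These are miRNAs of striated muscle. miR-183-5p was 227-fold and miR-134-3p, from a brain-rich imprinted cluster, 230-fold higher in CSF. The neuronal miRNAs miR-9-5p and miR-9-3p were 23.9-fold and 45.2-fold higher. In plasma the epithelial miRNAs miR-200a-3p and miR-141-3p were 54.2-fold and 24.4-fold higher, and the leukocyte miRNA miR-142a-3p was 8.58-fold higher.

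By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 593 of 1146 tested miRNAs differed between the fluids, 300 higher and 293 lower in CSF. The log2 fold change of the row labelled miR-206-3p was 8.30 ± 1.19 (SE, adjusted p = 1.7e-05), and that of the row labelled miR-1a-3p was 7.10 ± 0.88 (adjusted p = 4.16e-06). With the labels exchanged these were 7.11 for miR-206-3p and 8.30 for miR-1a-3p, both past the threshold. miR-134-3p (chromosome 12, 109734184 to 109734203, plus strand, exon of Mirg, mm10 throughout) stood at 7.85 ± 0.52 (adjusted p = 4.22e-09). miR-183-5p (chromosome 6, 30169711 to 30169732, minus strand, no host gene) stood at 7.83 ± 0.78 (adjusted p = 4.36e-07). miR-133b-3p (chromosome 1, 20682834 to 20682855, plus strand, exon of the lincRNA Gm28653) and miR-133a-3p (chromosome 18, 10782913 to 10782934, minus strand, intron of Mir133a-1hg) stood at 7.30 ± 0.73 and 7.27 ± 0.74. The near-identical miR-3473e and miR-3473b, whose CSF counts were nearly equal, were higher by 7.77 ± 0.67 and 6.89 ± 0.61. miR-1b-5p (6.61 ± 0.82) and miR-6947-5p (6.27 ± 0.49) complete the 10 largest rises.

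Among the 10 largest differences toward plasma, miR-200a-3p (chromosome 4, 156054911 to 156054932, minus strand, intron of Ttll10) was at -5.76 ± 0.69 (adjusted p = 2.91e-06) and miR-141-3p (chromosome 6, 124717917 to 124717938, minus strand, intron of Gm15884) at -4.61 ± 0.72 (adjusted p = 4.22e-05). miR-8092, within an untranslated exon of Zfp518a, was at -4.79 ± 0.47. The others were miR-7674-5p (-4.71), miR-5110 (-4.45), miR-185-3p (-4.35), miR-7066-3p (-4.22), miR-7221-5p (-4.19), miR-5119 (-4.10) and miR-8113 (-3.95). Of the most abundant miRNAs, miR-16-5p (-0.15 ± 0.62), let-7f-5p (-0.50 ± 0.60), let-7a-5p (-0.42 ± 0.53) and let-7c-5p (1.20 ± 0.66) did not pass, while let-7b-5p was higher in CSF (1.86 ± 0.57, adjusted p = 0.0106), although not with total-count scaling (0.19, adjusted p = 0.685). The red-cell miRNA miR-451a and miR-23a-3p were both higher in CSF, by 2.54 ± 0.52 and 2.26 ± 0.45, and lost their calls with that scaling (0.63, adjusted p = 0.202, and 0.75, adjusted p = 0.125).

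**Figure D2:**
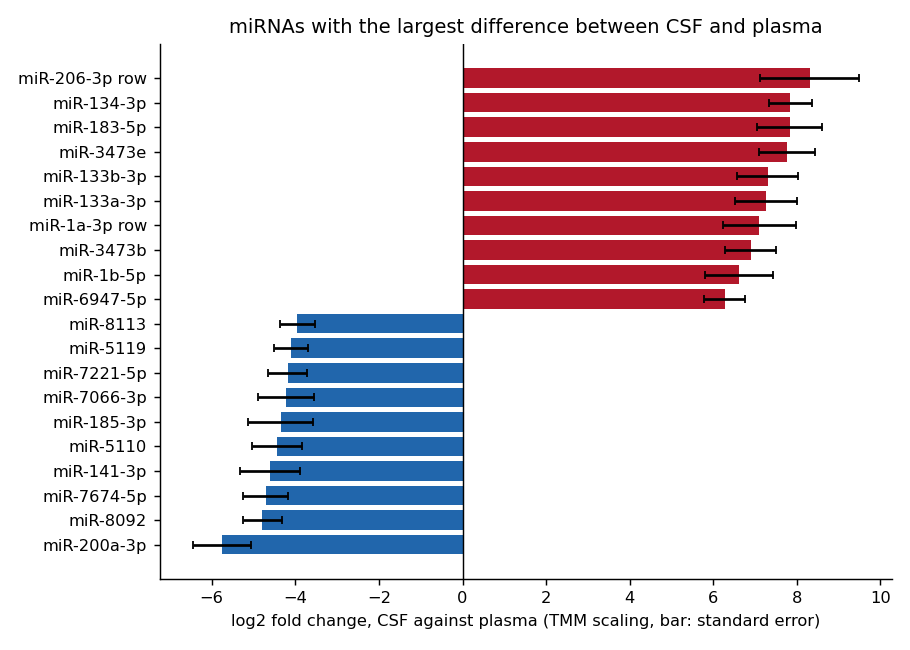
Log2 fold change of CSF against plasma with SE for the miRNAs with the largest differences past the threshold (4 libraries against 4, edgeR). Values run from 8.30 for the row labelled miR-206-3p to -5.76 for miR-200a-3p, and none of the 20 turned direction with total-count scaling.

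All 5 measured members of the muscle list were higher in CSF, also when adjusted over the list alone, with a median of 7.27, and it was the single list of 19 past the threshold by camera (adjusted p = 1.77e-05, adjusted p = 0.758 with an estimated correlation); 6 lists passed without the DOCA-salt female of plasma and 3 without the baseline male of CSF. Of 7 glial members 6 were higher, among them miR-125b-5p (1.62), miR-99a-5p (2.37 ± 0.48) and miR-23a-3p, while miR-27a-3p (-0.34) did not pass; the list missed the camera threshold (adjusted p = 0.0566). Of 10 neuronal members 5 were higher, or 6 adjusted over the list alone, with miR-9-5p at 4.58 ± 0.50 and miR-9-3p at 5.50 ± 0.47, while miR-128-3p (1.09) and miR-218-5p (0.02) did not pass (camera adjusted p = 0.0771). The choroid plexus and ciliated epithelium list, which shares the miR-200 family with the epithelial list, had 6 members lower and 1 higher of 9 (adjusted p = 0.0566). Its higher member was miR-204-5p, a choroid plexus miRNA (3.22 ± 0.46, adjusted p = 1.74e-05), and lower ones were miR-200c-3p (-3.26) and miR-34b-3p (-2.14 ± 0.40). The keratinocyte and other epithelium list split, with 3 higher (miR-183-5p and miR-203-3p, 1.68, among them) and 5 lower of 10 (adjusted p = 0.511).

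Blood-cell lists moved both ways. On the erythrocyte list 2 of 10 members were higher and 2 lower, with miR-486a-5p at -1.04 and miR-25-3p at -0.01 not past the threshold (camera adjusted p = 0.649). The leukocyte list had 1 higher and 3 lower of 9, including miR-142a-3p (-3.10 ± 0.45, adjusted p = 1.82e-05) and miR-150-5p (-2.21 ± 0.45, adjusted p = 4.43e-04), and its median of 0.02 and mean of -0.61 differed in sign (adjusted p = 0.615). On the platelet list 2 were higher and 1 lower of 6, with miR-199a-3p at 2.32 ± 0.57 (adjusted p = 0.649). Endothelial miRNAs had 3 higher and 3 lower of 7, miR-10b-5p at 3.39 ± 0.60 and miR-126a-5p at -1.55, with a median of -0.55 and a mean of 0.22 (adjusted p = 0.961). Smooth muscle had 2 of 5 higher, 1 adjusted over the list alone, with miR-145a-5p at 1.64 ± 0.38 (adjusted p = 0.449). Of 3 liver members 1 was higher, miR-192-5p (2.16 ± 0.35), while the hepatocyte miRNA miR-122-5p stood at -0.80 and did not pass (adjusted p = 0.649).

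Among the remaining lists, the renin-angiotensin-aldosterone and blood pressure list had 9 higher and 2 lower of 19, with miR-125a-5p at 1.51 ± 0.55 (camera adjusted p = 0.209). Inflammation had 4 higher and 1 lower of 9 (adjusted p = 0.649), and fibrosis 7 higher and 2 lower of 12, miR-29a-3p at 1.96 ± 0.54 (adjusted p = 0.0891). let-7 had 2 of 10 higher (adjusted p = 0.722). For miR-30, 4 of 5 were lower, miR-30e-5p at -2.23 ± 0.36 (adjusted p = 0.0566). The miR-17 family had 2 higher and 2 lower of 7 (adjusted p = 0.719). In the Dlk1-Dio3 imprinted cluster 6 were higher and 2 lower of 18, or 1 lower adjusted over the list alone, with miR-434-3p at 4.37 ± 0.50 and miR-379-5p at 2.06 ± 0.43 (adjusted p = 0.163). X-chromosome miRNAs had 4 higher and 3 lower of 22, or 3 and 1 adjusted over the list alone, with miR-532-5p at 2.15 ± 0.44 and miR-221-3p at -1.72 ± 0.35 (adjusted p = 0.744).

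The split between higher and lower depended on scaling. The median of all tested miRNAs was -0.12 with the trimmed mean of M-values (TMM) and -1.72 with total-count scaling, under which 797 miRNAs passed, 63 higher and 734 lower in CSF. Leaving out sign changes of miRNAs called with neither scaling, total-count scaling turned miR-125b-5p, miR-125a-5p, miR-203-3p, miR-191-5p, miR-10a-5p and miR-20a-5p, along with 8 others named in the closing section. Differences toward CSF shrank under it, to 6.37 for the row labelled miR-206-3p, 5.43 for that labelled miR-1a-3p, 5.56 for miR-133a-3p, 5.61 for miR-133b-3p, 6.47 for miR-183-5p, 6.39 for miR-134-3p, 2.79 for miR-9-5p and 3.85 for miR-9-3p, and those toward plasma grew, to -7.52 for miR-200a-3p and -4.79 for miR-142a-3p. Without 1 library miR-200c-3p moved to -2.05 (DOCA-salt male of plasma), miR-29a-3p to 1.28 (baseline male of CSF) and miR-125b-5p to 1.02 (DOCA-salt male of CSF, adjusted p = 0.169).

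DOCA-salt was compared with baseline in plasma over 4 libraries, with the sexes as a term. The muscle miRNA miR-206-3p was 6.38-fold higher after DOCA-salt, by 1.80 log2 in the female pair and 3.56 in the male pair. miR-346-3p, from an intron of the glutamate receptor gene Grid1, was 4.52-fold higher (1.05 and 3.57), and miR-7217-3p was 4.19-fold lower (-2.25 and -1.85). Neutrophil and platelet miR-223-3p stood 2.53-fold higher, from 4236 ± 153 to 11177 ± 4602 TMM-scaled CPM (SD, n = 2), and did not pass (adjusted p = 0.0772). The male baseline count of miR-206-3p is doubtful, as 98 UMIs came from 7999 reads, 81.6 reads per UMI against a library median of 7.58.

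The edgeR test with Benjamini-Hochberg adjustment passed 15 of 1398 miRNAs, 4 higher and 11 lower. miR-206-3p (chromosome 1, 20679055 to 20679076, plus strand, exon of Gm28653) had a log2 fold change of 2.67 ± 0.50 (adjusted p = 0.0041). miR-346-3p (chromosome 14, 34894662 to 34894683, plus strand) stood at 2.18 ± 0.57 (adjusted p = 0.0438), miR-7665-3p (chromosome 2, 120017558 to 120017579, intron of Mapkbp1) at 2.04 ± 0.52 (adjusted p = 0.0428) and miR-6388 (chromosome 12, 115695773 to 115695793) at 1.70 ± 0.45 (adjusted p = 0.0446). Lower after DOCA-salt were miR-7217-3p (chromosome 17, 27355778 to 27355799, exon of Gm49794; -2.07 ± 0.50), miR-8095 (chromosome 16, 22532128 to 22532149, intron of Dgkg; -2.07 ± 0.52), miR-466i-5p (-2.0), miR-3105-5p (-1.85), miR-12196-5p (-1.81), miR-6986-5p (-1.77), miR-376b-3p (-1.75) and miR-1933-3p (-1.64). The other 3 called, named after their values were seen because their mean was under 20 UMIs, were miR-6928-3p (-2.27), miR-704 (-2.07) and the neuronal miR-124-5p (-1.93). At an unadjusted p under 0.05 there were 192 miRNAs.

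**Figure D3:**
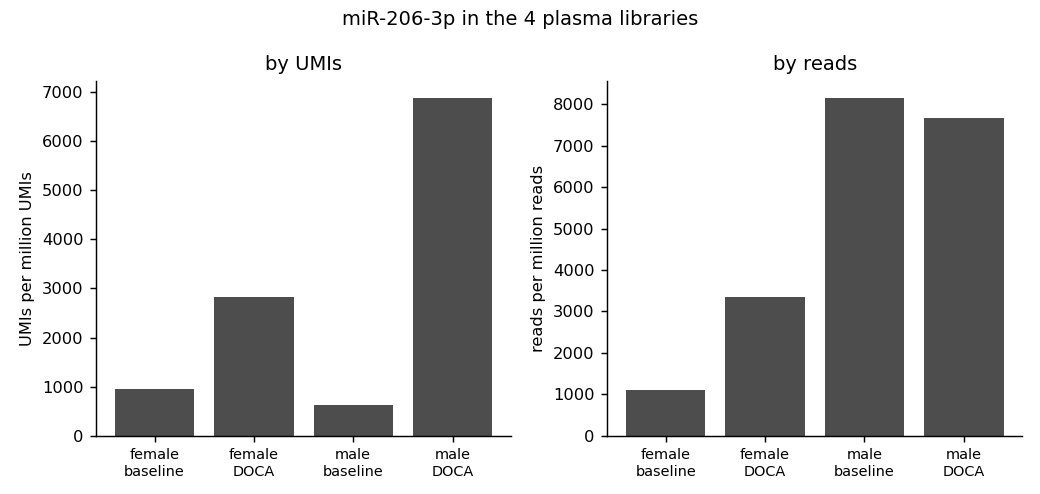
miR-206-3p in the 4 plasma libraries as CPM of UMIs (left) and of reads (right). By UMIs the baseline and DOCA-salt females stood at 950 and 2835 CPM and the males at 618 and 6882, and by reads the same libraries stood at 1104, 3360, 8154 and 7672.

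This count was unstable, and the median of all tested miRNAs moved from -0.03 with TMM to -0.19 with total-count scaling. The count was 29 with DESeq2's size factors in edgeR (16 higher and 13 lower) and 29 without the count filter (15 and 14), 1 by DESeq2's own test, and 0 with total-count scaling, with read counts, in the joint fit of both fluids and without the DOCA-salt female or the DOCA-salt male; it was 73 (57 higher, 16 lower) without the baseline female and 17 (8 and 9) without the baseline male. Without the baseline male miR-206-3p stood at 2.29 (adjusted p = 0.136), miR-346-3p at 1.05, miR-7665-3p at 1.22, miR-12196-5p at -0.93, miR-466i-5p at -3.02 and miR-8095 at 0.11. Without the baseline female miR-466i-5p stood at -0.29 (adjusted p = 0.933), miR-346-3p at 3.69, miR-7665-3p at 3.34 and miR-8095 at -3.13, and without the DOCA-salt male miR-3105-5p stood at -1.20. With read counts miR-206-3p stood at 0.93 (adjusted p = 0.538), over a range from 0.93 to 3.25 in 14 alternatives.

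Lists shifted toward DOCA-salt plasma in 4 cases by camera. Epithelial miRNAs had a median of 1.15 (adjusted p = 3.13e-04) although 0 of 11 members passed alone or over all miRNAs, with miR-200c-3p at 1.51, miR-141-3p at 1.26, miR-182-5p at 1.17 and miR-200a-3p at 1.15. Muscle miRNAs had a median of 0.99 (adjusted p = 0.00732) with 1 of 5 past the threshold, miR-206-3p, beside miR-133a-3p at 1.06, miR-133b-3p at 0.99 and miR-1a-3p at 0.76, whose ratio was -0.51 in females and 2.04 in males. The choroid plexus list had a median of 0.68 (adjusted p = 0.031) with 0 of 11 members past the threshold, with median ratios of 1.97 in the male pair and 0.18 in the female pair. The Dlk1-Dio3 cluster had a median of 0.55 (adjusted p = 0.031), with miR-127-3p at 1.20 and miR-379-5p at 1.13 not past the threshold, while the 1 of 20 that passed, miR-376b-3p, fell. None of these calls held when correlation was estimated (adjusted p = 0.999 with an estimated correlation for each). That setting could not decide, since within a fluid it called no list in simulations with a raised muscle list either. With read counts the epithelial list alone passed (adjusted p = 0.0117), as it did without the baseline male (adjusted p = 1.55e-04), while without the baseline female the muscle list alone passed (adjusted p = 0.0202), and without the DOCA-salt male the epithelial list stood at 0.283.

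The other 15 lists did not pass. On the neuron list (median -0.41, adjusted p = 0.142) 1 of 12 members fell, or 2 adjusted over the list alone. For erythrocytes (-0.13, adjusted p = 0.644) miR-16-5p stood at -0.24, miR-486a-5p at 0.15 and miR-451a at -0.50. Medians and adjusted p-values were 0.08 and 0.635 for platelets (2 members higher adjusted over the list alone), 0.05 and 0.988 for leukocytes (1 adjusted over the list alone), 0.12 and 0.768 for endothelium, and -0.17 and 0.999 for liver. They were 0.28 and 0.301 for inflammation (2 adjusted over the list alone), 0.31 and 0.301 for fibrosis, 0.14 and 0.635 for let-7 and -0.28 and 0.768 for the miR-17 family. For smooth muscle (-0.10), glia (0.08, 1 higher and 1 lower adjusted over the list alone), blood pressure (0.06), miR-30 (-0.06) and the X chromosome (0.09, 1 higher alone), adjusted p was 0.999 for each and the mean had the opposite sign.

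In CSF the same comparison asked what DOCA-salt changes in the fluid around the brain. miR-21a-5p, a miRNA of inflammation and fibrosis, stood 3.39-fold higher, from 1718 ± 529 to 5695 ± 18.9 TMM-scaled CPM (SD, n = 2), by 2.08 log2 in females and 1.45 in males, and did not pass (adjusted p = 0.0833). miR-10b-5p, from the Hoxd cluster, stood 3.01-fold higher (1.35 and 1.83, adjusted p = 0.0958), also short of the threshold. The count row labelled miR-1a-3p stood 3.48-fold higher (1.36 and 2.24, adjusted p = 0.0958) and that labelled miR-206-3p at -1.17 ± 0.53 (adjusted p = 0.468), so with the labels exchanged miR-206-3p would be the one at 1.80.

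Of 1036 tested miRNAs 2 passed by edgeR with Benjamini-Hochberg adjustment: miR-7231-5p (chromosome 6, 122831377 to 122831398, intron of Foxj2) rose by 2.59 ± 0.64 (adjusted p = 0.0266; 4.17 in females and 0.79 in males), and miR-188-5p (chromosome X, 7248031 to 7248051, intron of Clcn5), named after its values were seen since its mean was 17.5 UMIs, fell by 2.80 on the log2 scale (SE 0.66, adjusted p = 0.0266). The fall of miR-188-5p rested mainly on the male pair, with 55 UMIs at baseline and 5 after DOCA-salt. Its female pair fell short of the 50 UMIs needed for a ratio. At an unadjusted p under 0.05 there were 89 miRNAs. The lowest p-values not passing on the lower side belonged to miR-133a-5p (-1.87), miR-12192-5p (-1.77) and miR-770-5p (-1.74). DESeq2, size factors from DESeq2, total-count scaling, read counts and the joint fit each gave 0, and no more than 1 passed without any single library. miR-7231-5p ranged from 0.87 (without the DOCA-salt female) to 4.24 (without the DOCA-salt male) and passed in 3 of 14 alternatives.

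None of the 19 lists passed by camera in CSF. Adjusted over the list alone, 1 member was higher on each of the muscle, endothelial, blood pressure, inflammation and fibrosis lists, 1 muscle member was lower, and 1 X-chromosome member, miR-188-5p, was lower over all miRNAs as well. The lowest adjusted p, 0.197, was shared by the erythrocyte (median 0.51), epithelial (-0.81), blood pressure (0.29), inflammation (0.33) and let-7 (0.46) lists, with miR-486a-5p at 0.95, miR-203-3p at -1.03, miR-183-5p at -0.72 and let-7b-5p at 0.74. Glia followed at 0.48 (adjusted p = 0.204), then leukocytes at 0.29 and fibrosis at -0.05 with a mean of 0.29 (both 0.250). Muscle (-0.54), platelets (0.42) and choroid plexus (-0.29) had 0.275, endothelium (0.07) and the X chromosome (0.35) 0.363, and neurons (0.40) and Dlk1-Dio3 (0.15) 0.445. The miR-30 family (-0.20) had 0.563, liver (-0.13) and smooth muscle (0.14) 0.573, and the miR-17 family (-0.12, mean 0.01) 0.999. miR-133a-3p was at -0.05. Without the DOCA-salt female 12 lists passed, and without the baseline male 8.

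A test of whether the DOCA-salt effect differed between the fluids passed 0 of 1465 miRNAs by edgeR with Benjamini-Hochberg adjustment, with 113 at an unadjusted p under 0.05, and 1 by DESeq2. The lowest adjusted p was 0.115 for miR-206-3p, whose effect was lower in CSF than in plasma by -3.91 ± 0.85 under the deposited count labels. With the labels exchanged it stood at -0.94 ± 0.80 (adjusted p = 0.797) and with read counts at -2.02 ± 0.65 (adjusted p = 0.867), while its plasma side includes the doubtful male baseline count. It passed with DESeq2's size factors (adjusted p = 0.029), total-count scaling (adjusted p = 0.0185), no count filter (adjusted p = 0.00149), the erythrocyte list left out (adjusted p = 0.0294), DESeq2's test (adjusted p = 5.1e-04) and without each plasma library in turn. The test passed 2 without the baseline or the DOCA-salt male of plasma and 3 without the baseline or the DOCA-salt female of plasma.

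Within each sex 1 library stood against 1, so ratios carry no test. In plasma, of 703 miRNAs with at least 50 UMIs over the female pair, 45 were at least 2-fold higher and 25 lower after DOCA-salt, and of 673 in the male pair 116 were higher and 46 lower. With total-count scaling the female split was 18 and 57. Of 616 miRNAs counted in both sexes, 11 were higher in both (6.71 if the sexes were independent) and 3 lower in both (0.99). There were 0 opposite (2.28 higher in females alone and 2.93 in males alone if independent). Spearman's rho across miRNAs, which are not independent replicates, was 0.31. miR-206-3p (95% exact conditional intervals 1.61 to 2.01 in females and 3.28 to 3.88 in males), miR-148a-3p (1.12 and 1.02), miR-378a-3p (1.00 and 1.73), miR-2861 (1.71 and 1.24) and miR-346-3p were higher in both. miR-7217-3p, miR-880-3p (-1.04 and -1.25) and miR-511-5p (-1.10 and -1.25) were lower in both. miR-154-3p had 138 UMIs in the DOCA-salt male and 0 in the baseline male, a log2 ratio of at least 4.35 by the interval.

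In CSF 66 of 393 miRNAs were at least 2-fold higher and 24 lower in females, and 60 of 531 were higher and 55 lower in males. Of 377 counted in both sexes, 11 were higher in both (6.63 if independent) and 6 lower in both (2.23), with a rho of 0.16. Of the 9 opposite, 6 were higher in females and lower in males (5.66 if independent) and 3 the other way (2.61). miR-21a-5p, miR-10b-5p, the row labelled miR-1a-3p, miR-7032-5p (1.88 and 1.27) and miR-7058-3p (2.03 and 1.39) were higher in both. miR-6965-3p (-1.23 and -1.79), miR-6239 (-1.88 and -1.19), miR-5108 (-2.08 and -1.06), miR-7016-3p (-1.19 and -2.07) and miR-6356 (-1.32 and -1.06) were lower in both. The largest ratios were miR-7069-3p (4.65), miR-7231-5p (4.17) and miR-2861 (3.95) in females and miR-185-3p (3.95) and miR-188-5p (-3.56) in males.

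**Figure D4:**
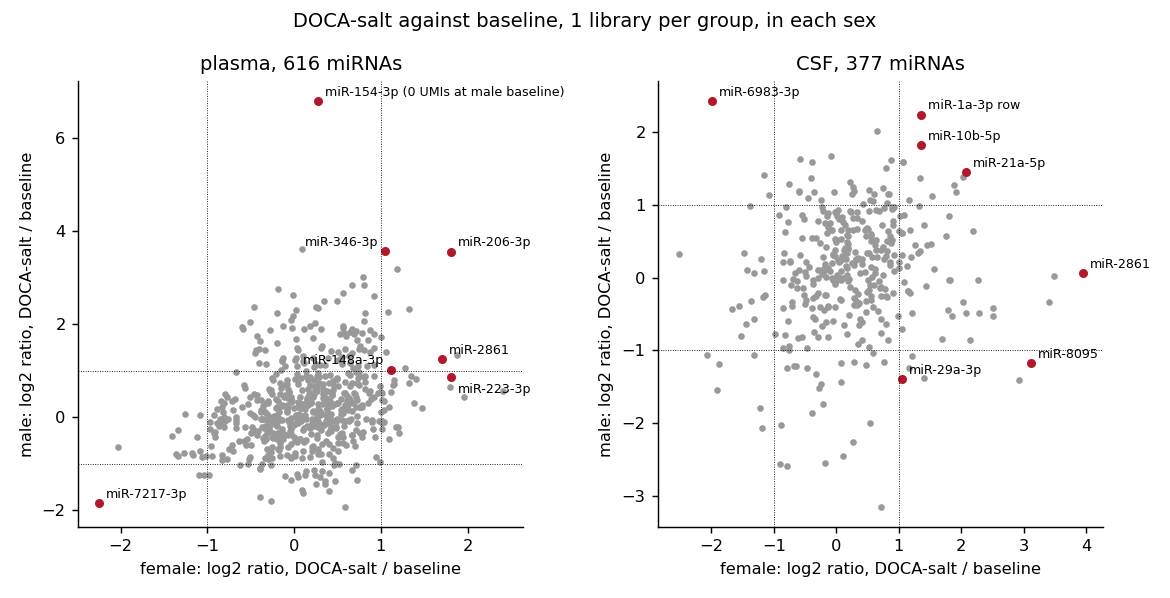
DOCA-salt against baseline log2 ratio in females (horizontal) and males (vertical) for miRNAs with at least 50 UMIs in each pair, in plasma (616) and CSF (377). Dashed lines mark a 2-fold change; miR-206-3p lies at 1.80 and 3.56 in plasma and miR-21a-5p at 2.08 and 1.45 in CSF.

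Sex was compared in plasma with treatment as a term. miR-8095, from an intron of Dgkg, was 5.26-fold higher in males (3.16 log2 at baseline, 0.84 after DOCA-salt, and 0.66 without the baseline male). The erythrocyte miRNAs miR-486a-5p (-1.11 ± 0.29) and miR-16-5p (-0.75 ± 0.20) stood lower in males without passing (adjusted p = 0.116 for each), and the epithelial miR-182-5p stood 3.71-fold higher (1.89 ± 0.51, adjusted p = 0.116), also short of the threshold.

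By edgeR with Benjamini-Hochberg adjustment 2 of 1398 passed, miR-8095 (2.40 ± 0.53, adjusted p = 0.0315) and miR-293-5p (2.69 ± 0.51, adjusted p = 0.00571), the latter named after its values were seen as its mean was 18.0 UMIs; 103 had an unadjusted p under 0.05, and DESeq2 gave 0. The epithelial list was higher in males by camera (median 1.25, adjusted p = 5.09e-05), with 6 of 11 members higher adjusted over the list alone and 0 over all miRNAs, such as miR-200c-3p (1.46) and miR-141-3p (1.42). The erythrocyte list was lower in males (median -0.72, adjusted p = 9.02e-05), with 3 of 10 lower adjusted over the list alone, and so was Dlk1-Dio3 (median -0.57, adjusted p = 0.019), with miR-127-3p at -0.74. The Dlk1-Dio3 difference lay in the DOCA-salt pair (median ratio -0.63, percentile 0.02 among random lists), against 0.039 (53.2) in the baseline pair. For this cluster the DOCA-salt female also stood above the baseline female (0.92, percentile 100), so that library weighs on both the sex and the DOCA-salt call. All 3 calls were lost with correlation estimated (adjusted p = 0.783 with an estimated correlation), a setting that called no raised list within a fluid in simulations. The epithelial call was also lost without the baseline female (adjusted p = 0.144), where 7 lists passed, all lower in males. No list passed without the DOCA-salt male, while 28 miRNAs did, against 5 without the baseline male and 0 without either female.

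The other lists had adjusted p between 0.0779 and 0.764 in plasma, and list medians are to be read against the median of all miRNAs, near 0 with TMM and 0.36 with total-count scaling. Fibrosis (-0.30, 2 lower adjusted over the list alone), let-7 (-0.36), glia (-0.37, 1 lower alone), leukocytes (-0.38), blood pressure (-0.29, 1 lower alone), inflammation (-0.37, 1 lower alone), the X chromosome (-0.22), muscle (-0.30), platelets (-0.33, 1 lower alone), the miR-17 family (-0.25), smooth muscle (-0.34), miR-30 (-0.23), liver (-0.11, mean 0.09) and endothelium (-0.21) had negative medians. Choroid plexus (0.16, 3 higher adjusted over the list alone) and neurons (0.05) had positive ones.

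In CSF males differed from females more widely. let-7c-5p was 5.70-fold higher in males, from 11127 ± 40.9 to 66405 ± 27884 TMM-scaled CPM (SD, n = 2), miR-26b-5p 5.74-fold, miR-125b-5p, a miRNA abundant in glia, 4.06-fold, and the red-cell miR-451a 4.33-fold. Muscle-related miR-1b-5p and miR-1a-1-5p were higher too. miR-8095 went the other way from plasma and was 15.4-fold lower in males (-1.77 log2 at baseline and -6.07 after DOCA-salt), and miR-5126 was 3.05-fold lower.

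The edgeR test passed 54 of 1036 miRNAs after Benjamini-Hochberg adjustment, 33 higher and 21 lower in males, with 182 at an unadjusted p under 0.05. The largest rises were miR-1b-5p (chromosome 18, 10785486 to 10785506, plus strand, intron of Mib1; 2.89 ± 0.51, adjusted p = 9.43e-06), miR-1a-1-5p (2.67 ± 0.54), the row labelled miR-206-3p (2.64 ± 0.56, adjusted p = 2.96e-04), miR-26b-5p (chromosome 1, 74394324 to 74394344, intron of Ctdsp1; 2.52 ± 0.49), let-7c-5p (chromosome 15, 85706616 to 85706637; 2.51 ± 0.51), the neuronal miR-132-3p (2.50 ± 0.57), let-7f-5p (2.47 ± 0.49), miR-190a-5p (2.40 ± 0.61), miR-30e-3p (2.33 ± 0.56) and the endothelial miR-126a-3p (2.23 ± 0.50). miR-451a was at 2.12 ± 0.50 and miR-16-5p at 2.0 ± 0.50. The largest falls were miR-8095 (-3.95 ± 0.63, adjusted p = 6.26e-07), miR-712-5p (-2.38), miR-3063-3p (-1.92), miR-367-5p (-1.89), miR-5131 (-1.87, from 1 library, and 0.05 without the DOCA-salt female), miR-6906-3p (-1.64), miR-5126 (-1.61), miR-6910-5p (-1.59), miR-6538 (-1.57) and miR-3072-5p (-1.56). With the CSF labels exchanged miR-1a-3p would pass in place of miR-206-3p. Without the DOCA-salt female, when none passed, the falls shrank to -2.22 for miR-8095, -1.13 for miR-712-5p, -1.12 for miR-3063-3p, -1.02 for miR-6906-3p, -0.97 for miR-5126, -0.72 for miR-6538 and -0.36 for miR-3072-5p. Without the baseline female miR-5131 stood at -3.54, miR-6538 at -2.36 and miR-3072-5p at -2.63, and without the baseline male miR-3063-3p at -1.16.

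**Figure D5:**
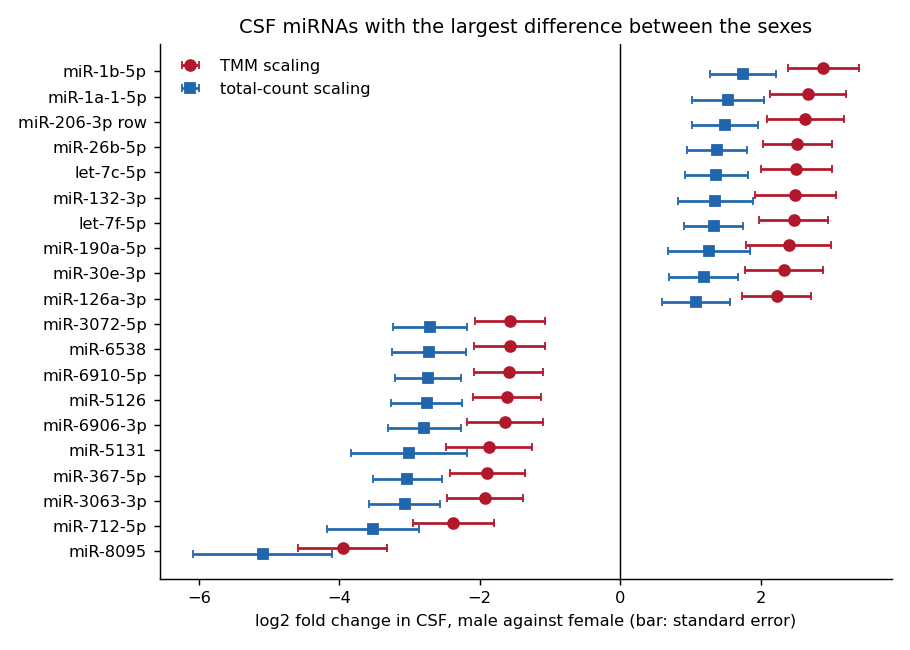
Log2 fold change of male against female CSF with SE for the miRNAs with the largest differences, with TMM and with total-count scaling (2 libraries against 2, treatment as a term). With TMM miR-1b-5p stood at 2.89 and miR-8095 at -3.95, and with total-count scaling at 1.75 and -5.09.

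By camera 13 of 19 lists were higher in male CSF, each losing its call with correlation estimated (adjusted p = 0.477 with an estimated correlation for the 13), and 8 lists passed without the baseline female. For let-7 (median 1.26, adjusted p = 7.6e-07) 4 of 10 rose, 6 adjusted over the list alone, let-7a-5p at 1.5 among them. For erythrocytes (1.16, adjusted p = 1.33e-05) 3 of 9 rose, 5 adjusted over the list alone. Blood pressure miRNAs (0.68, adjusted p = 1.33e-05) had 5 of 19 rising, including miR-29a-3p (1.55, and 0.83 without the baseline male) and miR-204-5p (1.60). Neurons (1.26, adjusted p = 2.72e-04) had 1 of 10, or 4 adjusted over the list alone, muscle (0.97, adjusted p = 2.98e-04) 2 of 6, fibrosis (1.07, adjusted p = 3.97e-04) 2 of 11, or 6 adjusted over the list alone, and miR-30 (1.29, adjusted p = 3.97e-04) 0 of 6, or 5 adjusted over the list alone. Inflammation (0.73, adjusted p = 0.00116) had 2 of 9, or 3 adjusted over the list alone, platelets (1.05, adjusted p = 0.0015) 1 of 6, or 2 adjusted over the list alone, glia (0.95, adjusted p = 0.00234) 2 of 7 and endothelium (0.83, adjusted p = 0.00522) 1 of 7, while the miR-17 family (0.79, adjusted p = 0.0156) and leukocytes (0.66, adjusted p = 0.0222) had 0. Lower in both pairs were muscle (70.45 and 71.8), blood pressure (75.3 and 62.25), glia (72.8 and 82.4) and endothelium (66.5 and 85.5). So were inflammation (75.4 and 65.75) and leukocytes (88.65 and 71.5). For these lists the shift was thus not far from that of miRNAs of like expression, and such ranks carry no test. Not passing by camera were the X chromosome (0.37, 1 member higher and 1 lower of 22, or 5 and 3 adjusted over the list alone), liver (0.57), choroid plexus (0.11), Dlk1-Dio3 (-0.02), smooth muscle (0.07) and epithelium (0.09, mean -0.09, with 2 of 6 lower adjusted over the list alone).

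Scaling and single libraries moved the CSF count. The median of all tested miRNAs was -0.06 with TMM and -1.20 with total-count scaling, which passed 359, 6 higher and 353 lower in males, and kept 6 of the 33 male-higher calls. Tested relative to the other miRNAs, which a common shift moves little, 11 of the 13 lists kept their call with that scaling, while leukocytes (adjusted p = 0.0799) and the miR-17 family (adjusted p = 0.0615) lost it. The count was 36 with DESeq2's size factors (27 higher, 9 lower), 25 by DESeq2 (21 and 4), 5 with read counts, 41 after thinning to equal total UMIs, 2 without the baseline female, 0 without the DOCA-salt female, 17 without the baseline male and 30 without the DOCA-salt male. A difference of the sex effect between the fluids, tested after the data were seen, passed 12 of 1465 miRNAs by edgeR with Benjamini-Hochberg adjustment, with miR-8095 at -6.23 ± 1.12 (CSF minus plasma, adjusted p = 0.00753), let-7c-5p at 3.08 ± 0.72 and miR-451a at 2.71 ± 0.65 (adjusted p = 0.037 for both).

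Between single libraries of each sex, without a test, 33 of 584 plasma miRNAs were at least 2-fold higher and 60 lower in the baseline male, and 31 of 741 higher and 37 lower in the DOCA-salt male, where total-count scaling gave 56 and 42 at baseline and 77 and 6 after DOCA-salt. miR-7044-3p (2.35) was among the highest at baseline and miR-7066-3p (-4.21) and miR-5110 (-3.47) among the lowest, and miR-7211-3p (3.36), miR-6932-5p (2.50), miR-200c-3p (2.42) and miR-182-5p (2.23) were highest after DOCA-salt. In CSF 81 of 409 were higher and 22 lower in the baseline male, and 106 of 501 higher and 74 lower in the DOCA-salt male, against 17 and 192 and 17 and 258 with total-count scaling. miR-29c-3p (3.14) and miR-126a-3p (2.95) were among the highest at baseline, and miR-185-3p (3.52) and miR-1b-5p (3.48) after DOCA-salt, where miR-8095 (-6.07) and miR-7069-3p (-5.18) were lowest.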

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

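The tests of reads behind miR-206-3p, of other muscle miRNAs in plasma, of plasma as a source of CSF muscle miRNAs and of muscle tissue in CSF, and the test of the sex effect between fluids, were chosen after the results were seen. In 138 groups of 4 libraries, 7 had 1 library standing apart by Dixon's ratio, the gap to the nearest library over the whole range, at its 95% critical value, which chance alone does in about 1 in 20 groups.

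The DOCA-salt male of plasma stood apart in the share of the choroid plexus list, at 0.947% (95% exact interval 0.913 to 0.982) against 0.219 to 0.279% in the other plasma libraries (ratio 0.917). It also stood apart in the share of miR-183-5p, 0.0916% (0.0811 to 0.103) against 0.0236 to 0.0347% (ratio 0.837), and in log2 CPM of miR-200a-3p, 10.71 against 8.36 to 8.69 (ratio 0.859). In the baseline male of plasma miR-7066-3p stood at 5.39 against 9.01 to 9.69 log2 CPM (ratio 0.841) and miR-6910-5p at 7.99 against 9.74 to 10.05 (ratio 0.850). The most abundant CSF miRNA took 44.7% (44.5 to 44.8) of the baseline male against 20.02 to 23.9% elsewhere in CSF (ratio 0.842). In the DOCA-salt female of CSF miR-5131 stood at 9.82 against 6.30 to 6.33 log2 CPM (ratio 0.992).

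The male against female log2 fold change differed between CSF and plasma, CSF minus plasma, for miR-8095 (-6.23, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.00753) and, each at adjusted p = 0.037, for let-7c-5p (3.08), miR-451a (2.71), miR-26b-5p (2.66), miR-1b-5p (2.97), let-7f-5p (2.79), miR-367-5p (-6.52) and miR-125b-5p (2.92). The DOCA-salt ratio went opposite ways in females and males of CSF, with no test of the difference, for miR-29a-3p (female minus male 2.44), miR-8095 (4.30), miR-219a-2-3p (-2.22), miR-6983-3p (-4.41) and miR-7578 (4.33). In the read columns, which the comparisons did not use, miR-206-3p in the baseline male of plasma had 81.6 reads per UMI against a median of 7.58.

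Muscle-list miRNAs filled 36.3 to 56.7% of CSF libraries. Plasma in the CSF is argued against as a source, since the highest share in plasma was 1.51%. Reads per UMI of the muscle list were at most 0.994 times those of the rest, so the list did not stand out in reads per UMI. CSF libraries had only 1.19 to 1.69 reads per UMI, too few for uneven amplification to show, so it stays open. Muscle tissue taken up while CSF was drawn may contribute and cannot be told apart from vesicles of muscle origin, as miR-499-5p and miR-208b-3p, also made in striated muscle, summed to 38 UMIs over the 4 CSF libraries, between the bounds set for either reading. Per library miR-499-5p had 3 to 7 UMIs in CSF and 5 to 12 in plasma. miR-208b-3p had 2 to 11 in CSF and 9 to 16 in plasma. Neither stood out in CSF, and counts this low cannot decide. Of 35 splits of the 8 libraries 1, the real one, called 593 or more, and the highest other called 0. Every other split puts both fluids in each group, so a large fluid difference becomes spread within groups. The splits therefore add no support beyond the test between the fluids. A difference between the fluids in the vesicles they carry stays open, as untested.

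miR-206-3p stood higher after DOCA-salt in plasma in both sexes by UMIs. In females a lost UMI count is argued against, since reads gave 1.86 against 1.80 from UMIs, and so is more muscle RNA of every kind, since the highest ratio among the other muscle miRNAs was 0.186. In males a UMI count too low for its reads in the baseline library could account for the rise, as reads gave a log2 ratio of 0.00727 against 3.56 from UMIs. Whether the UMI or the read value is off cannot be told. miR-1a-3p and miR-133a-3p also had their lowest plasma values in that library, at 1305 and 429 CPM of UMIs. More muscle RNA of every kind was not tested in males, where the muscle list, miR-206-3p included, had a median log2 ratio of 1.999. A DOCA-salt effect stays open in the female pair, where 1 library stands against 1. In the male pair it is not separable from the count or from more muscle RNA.

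Males and females differed in CSF in 54 miRNAs. Total depth is argued against as the whole cause, since 41 were called after thinning to the smallest total. Thinning equalises UMIs but not the number of miRNAs detected. Plasma carried into male CSF stays open. The upper quartile of the sex difference over 169 miRNAs higher in plasma was 0.367 against an erythrocyte-list median of 1.16. These values cannot decide it, because the 169 were called with the same male CSF libraries, which selects against miRNAs raised there. Scaling of the libraries cannot be told apart from a change in the miRNAs themselves, because total-count scaling moved the 33 male-higher calls by nearly the same amount (median -1.14, SD 0.00616) and so fixed that 6 stayed male-higher. Sex stays open as untested apart from library, with 2 libraries against 2.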

How the results depend on the processing

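Read counts in place of UMIs, exchanged CSF labels, the muscle list left out, a minimum mean of 100 UMIs and thinned libraries were chosen after the data were seen. The fluid comparison kept its count within 1.5 times except with the minimum of 100 UMIs, whereas each within-fluid count changed by more than that under most settings. Within a fluid the tests rest on 1 residual degree of freedom and on edgeR's prior degrees of freedom, which were 40.8 in plasma, where they ran from 4.27 to 27 in the 9 settings that gave 0 calls for DOCA-salt, 2 of them with a library left out, and infinite in CSF. Where the CSF value was finite, sex in CSF gave 0 calls at 2.41, 6.83 and 8.51, 2 at 7.67, 5 at 8.01, 30 at 27 and 36 at 76.5, but 359 at 10.1 with total-count scaling. Beyond the settings that test fewer miRNAs or libraries, the cause was not tested. With 3 libraries the lone library of a group is assumed to vary like the others. With condition as a block, which pairs the fluids by sex and treatment, fluid gave 601 calls, and the labels do not say whether a pair came from the same mice. Depth limits detection at 10 UMIs, which fell on thinning in each library but the smallest.

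For DOCA-salt in plasma, 15 miRNAs became 29 with DESeq2's size factors and 29 without the count filter, 1 by DESeq2's Wald test and 1 after thinning. It became 0 with total-count scaling, the erythrocyte list left out, the joint fit, only the term tested, read counts, the muscle list left out and the minimum of 100 UMIs. In CSF, 2 became 4 without the filter and 0 with DESeq2's size factors, total-count scaling, DESeq2's test, the joint fit, only the term tested, read counts, the muscle list left out, the minimum of 100 UMIs and thinning. For sex in plasma, 2 became 5 with DESeq2's size factors, 10 without the filter, and 0 with total-count scaling, DESeq2's test, the erythrocyte list left out, the joint fit, only the term tested, read counts, the muscle list left out, the minimum of 100 UMIs and thinning. In CSF, 54 became 359 with total-count scaling, 25 by DESeq2's test, 34 without the filter, 33 with the erythrocyte list left out, 30 in the joint fit, 5 with read counts, and 0 with only the term tested, the muscle list left out and the minimum of 100 UMIs. For the fluid effect, 593 became 152 of 205 tested with the minimum of 100 UMIs, which leaves fewer miRNAs to test. The difference of the DOCA-salt effect between fluids went from 0 to 2 with DESeq2's size factors, 2 with total-count scaling, 3 without the filter, 1 by DESeq2's test and 2 with the erythrocyte list left out.

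With each library left out in turn, calls ran from 531 to 587 for fluid, 0 to 73 for DOCA-salt in plasma, 0 to 1 for DOCA-salt in CSF, 0 to 28 for sex in plasma, 0 to 30 for sex in CSF, and 0 to 3 for the difference of the DOCA-salt effect between fluids. Lists past the camera threshold ran from 1 to 6 for fluid (6 without the DOCA-salt female of plasma, 3 without the baseline male of CSF), 1 to 3 for DOCA-salt in plasma, 0 to 12 for DOCA-salt in CSF, 0 to 7 for sex in plasma and 8 to 14 for sex in CSF.

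With an estimated correlation 0 lists passed for fluid, for DOCA-salt in plasma, for sex in plasma and for sex in CSF. Within a fluid this setting also called no raised muscle list in simulations, so it could not decide there. For fluid, 1 list became 3 without the filter, 5 with read counts and 0 with the muscle list left out, which removes the list itself. For DOCA-salt in plasma, 4 became 2 with only the term tested, 1 with read counts, 1 with the minimum of 100 UMIs and 2 after thinning. For sex in CSF, 13 became 1 with the minimum of 100 UMIs.

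Numbers of miRNAs at least 2-fold apart moved with the count minimum. With at least 20 UMIs, DOCA-salt in plasma gave 180 in females and 314 in males, and in CSF 183 and 207, while sex gave 219 at baseline and 158 after DOCA-salt in plasma and 211 and 290 in CSF. With at least 200 UMIs these were 21, 47, 35, 50, 28, 25, 53 and 91 in the same order. With read counts, DOCA-salt in plasma gave 357 in females and 543 in males and in CSF 181 in males, and sex in plasma gave 452 at baseline and 314 after DOCA-salt. Total-count scaling gave 209 at baseline and 275 after DOCA-salt for sex in CSF. The 14 plasma miRNAs moved the same way in both sexes became 9 with total-count scaling, 9 with a prior count of 5, 38 with at least 20 UMIs, 5 with at least 200 and 107 with read counts, and the 0 moved opposite ways became 8 with at least 20 UMIs and 29 with read counts. In CSF the 17 moved the same way became 28 and 8 with at least 20 and 200 UMIs, and the 9 opposite became 14 and 1.

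Counting only miRNAs with at least 10 UMIs, the 10 most abundant held 49.5% (plasma baseline female), 47.2% (plasma DOCA-salt female), 44.4% (plasma baseline male), 41.4% (plasma DOCA-salt male), 62.7% (CSF baseline female), 59.0% (CSF DOCA-salt female), 74.97% (CSF baseline male) and 73.3% (CSF DOCA-salt male). Detected at 10 UMIs were 1321, 1236, 1110 and 1401 miRNAs in plasma and 758, 806, 941 and 1077 in CSF in that same order of libraries. After thinning, detection at 10 UMIs gave 969, 807, 1110 and 993 miRNAs in plasma and 549, 528, 301 and 300 in CSF.

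Among miRNAs and lists called in the main or the alternative fit, directions reversed in few cases. Sign changes with no call in either fit were not counted, as for let-7c-5p between fluids, which ran from -0.74 to 1.61. For fluid, total-count scaling, which shifts all miRNAs toward plasma, turned miR-194-5p (-1.40), miR-191-5p (-0.11), miR-223-3p (-1.09), miR-342-3p (-0.996), miR-10a-5p (-0.0805), miR-143-3p (-1.34), miR-143-5p (-1.37), miR-145a-3p (-1.61), miR-218-5p (-1.79), miR-125b-5p (-0.23), miR-203-3p (-0.0442), miR-125a-5p (-0.15), miR-146a-5p (-1.43) and miR-20a-5p (-0.0593). With each library left out, miR-8095 under DOCA-salt in plasma ran from -3.13 to 0.11 (without the baseline male), and miR-5131 by sex in CSF from -3.54 to 0.04996 (without the DOCA-salt female). The median of the fibrosis list under DOCA-salt in CSF, relative to all miRNAs, ran from -0.67 to 0.75 (without the baseline male), with 0.21 without the DOCA-salt female. With exchanged labels the CSF ratio of miR-1a-3p was -0.81 in males and -1.53 in females. Across all alternatives the named miRNAs kept their side of the threshold 5229 times, which includes uncalled miRNAs that changed sign. They lost their call 425 times, gained one 59 times, and reversed with a call in either fit 16 times. Lists did so 1332, 56, 44 and 2 times, and pair ratios stayed within their interval 776 times, moved beyond it 43 times and reversed 2 times.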

Other observations

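The groupings in this part were chosen after the data were seen. Split by miRNA number, a rough guide to when a miRNA was entered in miRBase, 31 of 402 tested miRNAs numbered below 1000 were higher and 5 lower in male CSF by edgeR with Benjamini-Hochberg adjustment, with a median log2 fold change of 0.22. Among 634 numbered 1000 and above, 2 were higher and 16 lower, with a median of -0.19. The later-numbered miRNAs, many of them of low abundance, took 21.6% ± 3.21 of plasma UMIs and 10.1% ± 5.73 of CSF UMIs (SD, n = 4). Between fluids 130 of 433 numbered below 1000 were higher and 96 lower in CSF, against 170 and 197 of 713 numbered 1000 and above.

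List medians within single pairs, which carry no test, were ranked among 10000 random lists of like expression. After DOCA-salt in plasma the male pair had medians of 1.999 for the muscle list (4 members, percentile 99.95), 1.66 for the epithelial list (10 members, 99.96) and 1.97 for the choroid plexus list (6 members, 99.9), against 0.15 (23.1), 0.38 (80.9) and 0.18 (43.6) in the female pair. For the Dlk1-Dio3 cluster, imprinted miRNAs expressed from the maternal chromosome, the female plasma pair had 0.92 (percentile 100) and the male pair 0.37 (85.8), while in CSF the male pair had 0.82 (99.9) and the female pair -0.38 (7.0). Whether the sexes differed in these lists was not tested.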
